A study of Sciaenops ocellatus with 24 samples.

How the data were processed

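The samples were pools of whole red drum (Sciaenops ocellatus) larvae taken 48 hours post fertilization, per the labels, from 2 exposure experiments with Deepwater Horizon oil. In each experiment 3 concentrations of a high-energy water accommodated fraction, which is seawater blended with oil, were set against that experiment's own control. Small RNA was isolated from the pools with miRNeasy kits, made into libraries with a NEBNext small RNA kit and sequenced on a NextSeq 500, per the labels. The 24 libraries formed 8 groups of 3. Nothing in the labels says that the replicates came from separate spawns or tanks, so the p-values measure only the spread between these samples, which may be technical.

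The authors deposited 6 tables of whole-number read counts, 1 per oil and concentration, each with the 3 exposed and the 3 control libraries of that oil. The features are mature miRNA names from miRBase, per the file headers, and carry the prefixes of many species (ola for medaka, dre for zebrafish, ssa for Atlantic salmon, chi for goat and others). No red drum miRNA annotation was used here. The aligner, the miRBase release and the rule for reads that fit several names are not given in the sources used here. Reads of 1 red drum miRNA can therefore be split between, or counted under, names of several species. A name below stands for the reads counted under it, and its arm (5p or 3p) is the one in the name. The arm was not checked against reads and may be wrong. mdo-miR-24-3p and fru-miR-24-5p, for example, had the same counts in the slick controls (2980, 4698 and 4909).

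The tables held 193 to 205 names. Each listed name had at least 1 count in control library 1 of its oil, so a miRNA found only in exposed larvae would not be listed. Between 38.0% and 43.4% of the names of a table were at 0 in at least 1 library. The count columns of controls 2 and 3 were the same in the 3 tables of an oil, whereas control 1 differed at 7 names for slick oil and 3 for source oil. Those names were left out of fits across tables, which kept 185 names for slick and 190 for source oil. All columns were matched to samples by their labels, and 0 columns stayed unmatched.

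The authors also deposited 1 DESeq2 table per comparison. The submitters' processing notes name DESeq2 without a version. Per the file headers, these tables hold a mean signal of the control and of the exposed libraries (counts divided by size factors, from the values), and a deposited score that is the difference of both means. They also hold the authors' log2 fold change, which is shrunken for low or variable names, from the values, and the authors' p-value and adjusted p-value (FDR). These tables were used only to set the authors' calls, means, log2 fold changes and the correlations of the latter beside the present values.

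Differential abundance was tested with edgeR 4.0.16 in R 4.3.3 on the counts as deposited, with TMM normalization and the quasi-likelihood F test (glmQLFit and glmQLFTest). Names with at least 10 counts in at least 3 libraries were tested, and Benjamini-Hochberg adjusted p-values under 0.05 were calls. Each oil and concentration was fitted against its control within its own table, with no covariate. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of the F statistic. CPM were taken over the tested names and scaled by TMM within that fit, and are given as mean ± SD over the 3 libraries of a group. The SD and n = 3 hold for every group value below unless another n is given. Further fits tested the slope on concentration over the 12 libraries of an oil (per highest concentration, with the control at 0) and the difference between the slick and the source response at the matched rank of concentration. The last fit compared the 2 sets of controls. The percent loadings of the oils differ, so only ranks match.

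These choices, the miRNA lists and the rule for named miRNAs were fixed before the data were examined. A second set of fits was chosen after seeing that a name could be at 0 in some libraries and at high counts in others, which raised the common biological coefficient of variation of the 6 comparisons to between 124% and 139%. It used only names counted in every library of the fit, where this coefficient was 11.4% to 36.7%. Uneven counts remained in it, such as aca-miR-26-5p at 501772, 7930 and 767498 in the slick controls. In slick control 1 mdo-miR-10b-5p was at 10880 and sha-miR-10b at 15541, names nearly equal in the source controls. Both sets are given, and the second is always named as such. A name that disappears altogether in 1 group can be called only in the first.

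The 16 miRNA lists were defined by miRNA number with any species prefix. They were heart and skeletal muscle, the nervous system, sensory organs and eye, skin and other epithelia, blood cells and vessels, liver and gut, pancreas and endocrine cells, and cartilage with smooth muscle and connective tissue. The other lists were the let-7, miR-17-92, miR-430, miR-29 and miR-30, and miR-15/16 families, the Hox cluster miRNAs, hypoxia and damage response miRNAs, and the miR-23/24/27 cluster. Lists with at least 3 measured members were tested against the other names with camera in limma 3.58.1 on log2 CPM, two-sided, with a preset correlation of 0.01 and adjustment over lists. Camera was repeated with an estimated correlation, and fry tested whether the members of a list moved one way on balance.

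The rule for named miRNAs took, per oil and concentration, the calls whose 3 exposed libraries lay on 1 side of the control mean, up to the 12 with the largest change in each direction. With fewer than 5 such calls it took also the 5 names with the smallest p. It added up to 4 called members of each list, names called in the same direction in both oils, the 10 most abundant names of the controls, and up to 10 names with the smallest adjusted p in the fits across oils and concentrations. Where the rule was applied to the second set of fits, it was unchanged.

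The total count per library lay between 2820454 and 9741582. The self-test drew counts at the means and library sizes of each comparison and changed 40 names, 20 by a fold of 1.5 and 20 by a fold of 2, in 10 simulations. Changed names were drawn only from names counted in every library whose mean count passed a further minimum. Observed zeros were kept at 0. The shares recovered therefore do not cover low names or names with zeros. With all names in the fit, 2-fold changes were recovered in 18.5%, 0% and 63.5% of cases for slick oil 1.25%, 2.50% and 5.00%. The shares were 98%, 90.5% and 97% for source oil 0.135%, 0.27% and 0.54%. With names counted in every library the shares were 85%, 15% and 93.5% for slick oil, and 99.5%, 100% and 100% for source oil. For changes of 1.5-fold these fits recovered 32%, 2% and 54% for slick oil and 90%, 85.5% and 88% for source oil. Among pairs of libraries of 1 group the chi-square per degree of freedom was at least 114, so no library was counted as a duplicate.

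The replicate numbers of the labels were checked for pairing by the correlation of each exposed library's deviations from its group mean with those of the control of the same number. In slick oil 2.50% all 3 correlations exceeded 0.1 (0.47, 0.68 and 0.47), and each library matched best with the control of its own number, so a fit with the replicate number as a block was computed there. It also gave 0 calls. In the other 5 comparisons this rule was not met, so no pairing was assumed, although 3 libraries a group cannot exclude it. Alternatives computed for the fits were RLE size factors, library totals alone, no count filter, at least 50 counts, DESeq2 1.42.0, the replicate block, an adjusted p under 0.10, all 12 libraries of an oil in 1 fit, the rank of concentration for the slopes, and leaving out each library in turn. A correlation of fold changes between comparisons with shared controls was set beside 200 simulations of unchanged groups. Floors cover counting error only, since the reads carry no molecular identifiers.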

Results

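Small RNA of whole red drum larvae was profiled at 48 hours post fertilization after exposure to 1 of 2 oils of the Deepwater Horizon spill. Slick oil had weathered at sea and was skimmed from the Gulf surface, and source oil was a pipeline oil standing in for the oil as it left the well. Slick oil was given at 1.25%, 2.50% and 5.00% and source oil at 0.135%, 0.27% and 0.54% of the oil-in-seawater preparation. Each oil had its own control group, and all 8 groups had 3 libraries of pooled larvae. The total count per library was 8000563 to 9039983 in the slick controls and 4440488 to 9306948, 4851955 to 7856249 and 2820454 to 4346165 at 1.25%, 2.50% and 5.00% slick oil. It was 6778108 to 9404688 in the source controls and 7336908 to 8751205, 6842201 to 8761901 and 7285368 to 9741582 at 0.135%, 0.27% and 0.54% source oil. The slick 5.00% libraries were thus the shallowest.

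Unexposed larvae were dominated by miRNAs of nerve and muscle. Over the 6 control libraries and the names listed for both oils, aca-miR-9-5p, of a family expressed in the developing brain, took 25.8% ± 5.26 of the counts (SD, n = 6). The skeletal muscle miRNA ssa-miR-206-5p took 16.02% ± 3.28. Both shares differed between the experiments, with 29.59% and 14.01% in the slick and 21.99% and 18.04% in the source controls. Other large shares were those of the neuronal mdo-miR-128a-5p with 5.03% ± 1.64, ola-miR-21 with 4.96% ± 0.80, ola-miR-181a-5p with 3.20% ± 0.60 and chi-miR-182, a miRNA of sensory cells, with 2.09% ± 0.32. Smaller shares fell to cfa-miR-181b (1.20% ± 0.15) and sha-miR-92a (1.17% ± 0.28). The mean shares of ola-miR-128 (3.22% ± 2.97) and mmu-miR-183-5p (1.66% ± 2.65) rested on some libraries only, since these names were at 0 in 2 and 4 of the 6 control libraries, and where ola-miR-128 was counted it had nearly the same counts as mdo-miR-128a-5p. Names listed for only 1 oil also held large shares, aca-miR-26-5p 4.73% ± 4.28 and sha-miR-181a-5p 3.41% ± 0.80 of the slick controls (nearly the same counts as ola-miR-181a-5p), and chi-miR-183 4.32% ± 3.77 and cgr-miR-26a 4.21% ± 3.77 of the source controls, both source names at 0 in 1 library (n = 3; these 4 were named after their values were seen).

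The question of each of the first 6 comparisons was which miRNAs differed between larvae exposed to 1 concentration of an oil and the unexposed larvae of the same experiment. At the matched rank of concentration source oil gave more calls than slick oil in the plot of higher and lower names per comparison. The exception was the lowest rank among names counted in every library, where both gave 0.

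**Figure D1:**
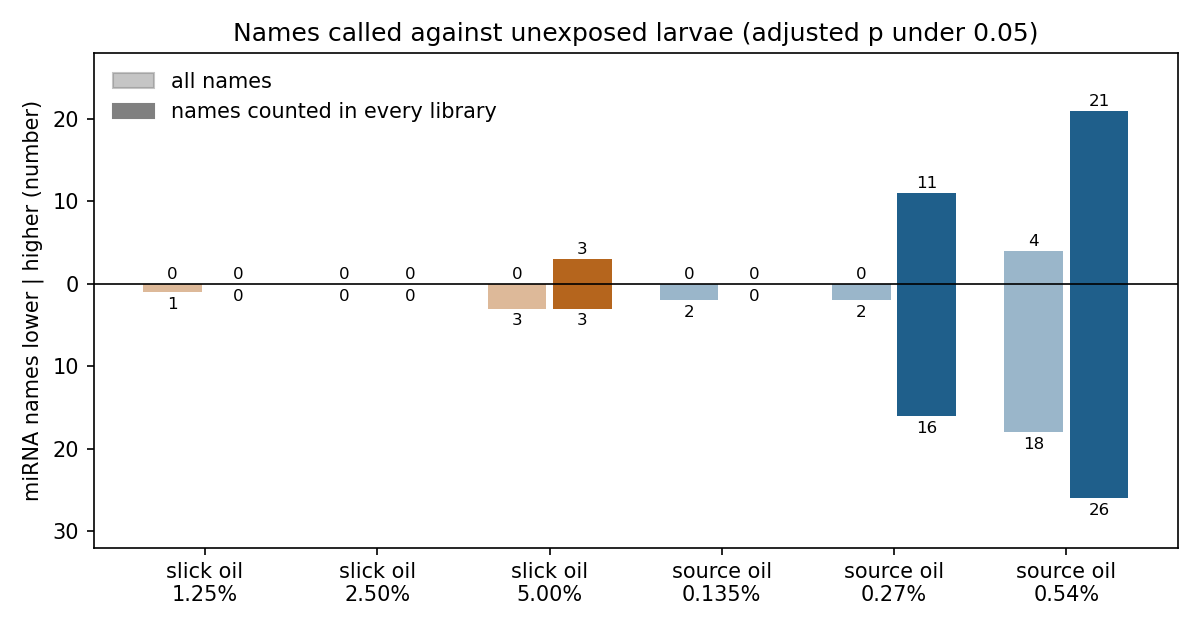
Number of miRNA names higher (above 0) and lower (below 0) than the control in each of the 6 comparisons of 3 exposed with 3 control libraries (edgeR, adjusted p under 0.05), with all names in the fit (pale bars) and with names counted in every library (dark bars). The bars are longest for source oil 0.54%, with 4 higher and 18 lower names of 153 tested in all, and 21 higher and 26 lower names of 119 counted in every library.

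At 0.54% source oil, 3 of 4 names of the eye and sensory organs, 2 erythroid names and 5 let-7 names were lower, and 6 of 10 miR-17-92 names were higher. ola-miR-184-5p, a miRNA of the lens and cornea, fell from 11230 ± 1460 to 5244 ± 553 CPM, a log2 fold change of -1.10 ± 0.12 (SE, adjusted p = 0.000991, n = 3 against 3, edgeR). ola-miR-204, another eye miRNA, fell by 0.78 ± 0.12 on the log2 scale and chi-miR-182 by 0.46 ± 0.07, both with adjusted p = 0.00399. The erythroid ssa-miR-144-3p fell from 238 ± 27.1 to 118 ± 2.15 CPM, with a log2 fold change of -1.02 ± 0.12 and adjusted p = 0.000991. Its genomic neighbour miR-451, as chi-miR-451-5p, fell by 0.73 ± 0.13 on the log2 scale, at the low level of 14.7 ± 0.11 CPM in the controls. These values come from the fit to names counted in every library, which called 21 higher and 26 lower names of 119. Over all 153 names edgeR called 4 higher and 18 lower names, 21 of which were also called in that fit. The exception was tni-let-7d, counted at 61026, 61584 and 51151 in the controls and at 0 in every exposed library. Its level was at least 62000-fold lower, against a floor of 3 counts over the group (adjusted p = 0.000207 over all names). mse-let-7a, another let-7 name, was counted in every library, with authors' means of 71590 in the controls and 56250 with exposure. The zeros therefore hold for the name tni-let-7d, not for let-7 reads as a whole.

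All 5 let-7 names counted in every library, a family whose level rises as animals develop, fell at 0.54% source oil (5 also when adjusted over the list alone). mse-let-7a and tca-let-7-5p have nearly the same counts, so the tally and the list test count that signal as 2 names. ssc-let-7i changed by -0.56 ± 0.09 on the log2 scale and ola-let-7g by -0.48 ± 0.10, with adjusted p of 0.00434 and 0.00696. The median of the list was -0.43, and -0.20 under library totals alone, where 2 of the 5 were called lower. Camera gave the list an adjusted p of 0.0213, and 0.475 with an estimated correlation. Over all names 5 of 8 let-7 names were called lower, 6 when adjusted over the list alone, with a camera adjusted p of 0.00117, and 0.285 with an estimated correlation. This tally and this camera test include tni-let-7d, which was at 0 in every exposed library.

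Of 10 names of the miR-17-92 family, which is tied to cell proliferation, 6 rose and 2 fell (6 and 3 adjusted over the list alone). The highest of them were ola-miR-19b and ssa-miR-19c-4-5p, near-identical names that each changed by 0.78 ± 0.12 (adjusted p = 0.00399). dre-miR-93 changed by 0.58 ± 0.13, ola-miR-106a by 0.53 ± 0.12, ola-miR-17 by 0.52 ± 0.15 and oan-miR-20a-5p by 0.43 ± 0.11. sha-miR-92a and hsa-miR-25-5p went the other way, with -0.54 ± 0.12 and -0.39 ± 0.13. The camera adjusted p of the list was 0.12, its median was 0.47, and under library totals alone 7 names were higher and 0 lower. Over all names ola-miR-19b and ssa-miR-19c-4-5p were the 2 called members.

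Among the other lists at 0.54% source oil, 3 of 4 sensory organ and eye names fell, and the fourth, chi-miR-96, was at 0.08 ± 0.09 (camera adjusted p = 0.0522, and 0.475 with an estimated correlation). The Hox cluster list had 3 of 5 names lower, and all 5 when adjusted over the list alone, among them sha-miR-10b (-0.51 ± 0.11, adjusted p = 0.0076) and mdo-miR-10b-5p, which has nearly the same counts. Its median was -0.51, and camera gave an adjusted p of 0.0392, and 0.475 with an estimated correlation. The blood cell and vessel list had 2 of 6 lower, the erythroid names above, while its median was 0.07, its mean -0.16 and the direction of its camera test down (adjusted p = 0.481). In muscle, ssa-miR-206-5p fell by 0.53 ± 0.11 on the log2 scale (adjusted p = 0.0076, from 252900 ± 14200 to 175300 ± 20400 CPM), rno-miR-133b-5p rose by 0.76 ± 0.22 (adjusted p = 0.0279), and ggo-miR-499a was at 0.09 ± 0.11. The nervous system list had 2 of 8 lower, the neuronal aca-miR-132-5p (-0.58 ± 0.10) and mdo-miR-128a-5p (-0.82 ± 0.21), with a median of -0.16 that turned to 0.06 under library totals alone. All 8 names of the miR-23/24/27 cluster had positive log2 fold changes with a median of 0.27, and 1 of them, ssa-miR-23b-5p, was called (0.28 ± 0.09, adjusted p = 0.0405, and 0 adjusted over the list alone). The 8 include 3 miR-24 names with the same counts in most libraries, fru-miR-24-5p and ssa-miR-24a-4-5p in all. Camera, which counts them separately, gave this cluster an adjusted p of 0.0289, and 0.475 with an estimated correlation.

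The liver and gut list had ssa-miR-194b-5p lower (-0.71 ± 0.13, adjusted p = 0.00559) and ola-miR-194-5p not called. In the pancreas and endocrine list ipu-miR-375, a miRNA of islet cells, fell by 0.56 ± 0.10 and tgu-miR-217-5p rose by 0.34 ± 0.10 on the log2 scale. aca-miR-34b-5p, of a family induced by p53, rose from 34.5 ± 5.27 to 69.0 ± 17.0 CPM (1.00 ± 0.20, adjusted p = 0.0076), and ola-miR-21 of the same list was at 0.26 ± 0.11 (called when adjusted over the list alone). efu-miR-29b had a log2 fold change of 1.66 ± 0.42 at the very low level of 0.68 ± 0.28 CPM in the controls (adjusted p = 0.0159), and oar-miR-30d was not called. Of 4 cartilage and connective tissue names ola-miR-214 was higher (0.48 ± 0.16, adjusted p = 0.0394, 0 adjusted over the list alone). ola-miR-430a, of a family that clears maternal mRNA in the early embryo, had a log2 fold change of 0.34 ± 0.11 and an adjusted p of 0.0405, and was called in 1 of the 6 fits that left out a library. None of the 5 skin and epithelium names was called, with log2 fold changes between 0.07 and 0.24, nor was aca-miR-16a-5p of the miR-15/16 family (-0.04 ± 0.10). Among names outside the lists, ola-miR-100 (-0.69 ± 0.13) and ssa-miR-222a-5p (-0.69 ± 0.18) fell, whereas rno-miR-3570 (1.03 ± 0.24), ccr-miR-722 (0.55 ± 0.13), ipu-miR-107b (0.59 ± 0.16) and ssa-miR-8159-5p (0.39 ± 0.08) rose.

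In 76 of the 153 names the 3 exposed and the 3 control libraries did not overlap, where chance gives 10%. The same held for 14 of 159, 17 of 156 and 31 of 149 names for slick oil from low to high. It held for 35 of 156 and 55 of 158 names at 0.135% and 0.27% source oil. DESeq2 called 64 of all names, and the authors' deposited table called 32 higher and 31 lower names, which include all 22 and all 47 calls. Under library totals alone the median log2 fold change of all names moved from -0.03 to 0.28 and the split turned to 25 higher and 5 lower. It turned to 43 higher and 14 lower among names counted in every library. The count over all names rested on single libraries: it was 8, 0 and 1 without control 1, 2 or 3 and 2 without exposed library 2, 5 without a count filter and 34 with all 12 libraries of the oil. The 47 calls fell to 29 without control 2 and 27 without control 3, and ola-miR-184-5p, ola-miR-204, chi-miR-182, ssa-miR-144-3p and chi-miR-451-5p were called in each of the 6 fits that left out a library. Among weaker names ola-miR-17 and ssa-miR-222a-5p were called in 2 of these 6 fits, rno-miR-133b-5p in 3, tgu-miR-217-5p and ola-miR-214 in 1 and ssa-miR-23b-5p in 0.

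At 0.27% source oil ola-miR-184-5p, ssa-miR-144-3p and ola-miR-204 were again lower, whereas chi-miR-182 (adjusted p = 0.0839) and chi-miR-451-5p (adjusted p = 0.391) were not called. ola-miR-184-5p fell from 11820 ± 1650 to 6247 ± 392 CPM (-0.92 ± 0.11, adjusted p = 0.00495, names counted in every library), and it also fell over all names (-0.90 ± 0.10, adjusted p = 0.0366). ssa-miR-144-3p changed by -0.58 ± 0.12 and ola-miR-204 by -0.73 ± 0.17 (adjusted p = 0.0227 for both), and ssa-miR-206-5p by -0.42 ± 0.10 (adjusted p = 0.0229). Among the higher names were aca-miR-34b-5p (0.78 ± 0.19, adjusted p = 0.0277) and, at under 3 CPM, efu-miR-29b (1.52 ± 0.29, adjusted p = 0.022). mdo-miR-128a-5p changed by -0.80 ± 0.16 with adjusted p = 0.022, and hsa-miR-130b-5p by -0.45 ± 0.12 with adjusted p = 0.0365.

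By list, 5 of 10 miR-17-92 names rose and 1 fell (6 and 1 adjusted over the list alone), led by ola-miR-19b (0.53 ± 0.12), ola-miR-17 (0.52 ± 0.09) and ola-miR-106a (0.48 ± 0.09). Of 4 let-7 names 3 fell (3 adjusted over the list alone), with ola-let-7g at -0.32 ± 0.09 and ssc-let-7i at -0.34 ± 0.10. Of 4 sensory organ and eye names 2 fell (3 adjusted over the list alone). Of 5 Hox cluster names 2 fell (3 adjusted over the list alone), both of them miR-10b names that have nearly the same counts. The medians of the let-7 and Hox lists were -0.32 and -0.30, and -0.13 and -0.12 under library totals alone, where 0 names of either list were called lower. Camera gave both lists an adjusted p of 0.0496, and 0.56 and 0.507 with an estimated correlation. Over all names camera called the let-7 family (0.0144), the Hox cluster (0.0225) and the miR-23/24/27 cluster (0.0384), with adjusted p of 0.556, 0.556 and 0.777 with an estimated correlation. The let-7 test over all names includes tni-let-7d, which was at 0 in every exposed library.

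At 0.27% source oil edgeR called 11 higher and 16 lower of 115 names counted in every library. Over all 158 names it called 0 higher and 2 lower, ola-miR-184-5p and tni-let-7d, the latter at 0 in every exposed library and at least 58100-fold lower. The let-7 name mse-let-7a was still counted in every library, with authors' means of 68710 in the controls and 54200 with exposure. DESeq2 called 31 over all names and 28 with names counted in every library, and the table the authors deposited had 10 higher and 23 lower names. Under library totals alone the median of all names was 0.22 and the split 31 higher and 2 lower with names counted in every library, and 9 and 1 over all names. The 27 calls became 17, 2 and 1 without control 1, 2 or 3, and 43, 1 and 6 without exposed library 1, 2 or 3. The 2 calls over all names became 6, 1 and 0 without control 1, 2 or 3, 1 without a count filter and 13 with all 12 libraries.

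At 0.135% source oil the calls over all names were 2 names listed at 0 in every exposed library. tni-let-7d was again at 0 in every exposed library, at least 60400-fold lower (adjusted p = 0.000359). The let-7 name mse-let-7a was at 62779, 65444 and 56515 counts in the controls. With exposure it was at 71873, 69487 and 64720 (-0.035 ± 0.061, not called). ola-miR-125a-5p was counted at 14625, 15861 and 16332 in the controls and at 0 in the exposed libraries, at least 16500-fold lower (adjusted p = 0.000954). This name was not among the calls at 0.27% or 0.54% source oil, by edgeR or by the authors. The next smallest p over all names belonged to mdo-miR-10b-5p and sha-miR-10b (-0.27 ± 0.05 and -0.26 ± 0.05, adjusted p = 0.166 for both) and tgu-miR-217-5p (0.24 ± 0.05, adjusted p = 0.184). In the names counted in every library 0 of 114 were called by edgeR, 27 had an unadjusted p under 0.05 and DESeq2 called 13. Its smallest p-values were those of ola-miR-184-5p (-0.53 ± 0.12), ssa-miR-734-5p (0.49 ± 0.12) and efu-miR-27b (0.44 ± 0.11), each with adjusted p = 0.0952.

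All 8 miR-23/24/27 names had positive log2 fold changes at 0.135% source oil, with a median of 0.23 and 0 calls among all names, but 6 higher when adjusted over the list alone. The 3 miR-24 names among them share most or all of their counts and are tallied and tested separately. Camera gave this cluster an adjusted p of 0.00247, and 0.443 with an estimated correlation (0.00249 and 0.608 over all names). The 2 calls over all names became 1 without control 2, 0 without control 3 and 4 without exposed library 3, and DESeq2 gave 23. Among names counted in every library there were 9 calls without control 1 and 1 without exposed library 3. The authors' deposited table had 13 higher and 9 lower names, and library totals alone moved the median of all names to 0.11.

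At 5.00% slick oil the erythroid ssa-miR-144-3p again fell, from 343 ± 36.1 to 113 ± 26.3 CPM. Its log2 fold change was -1.60 ± 0.20 with names counted in every library (adjusted p = 0.00218) and -1.58 ± 0.21 over all names (adjusted p = 0.0338). Also lower were dre-miR-124-4-5p, a miRNA of neurons (-0.83 ± 0.17, adjusted p = 0.0286), and ssa-miR-18a-5p of the miR-17-92 family (-0.65 ± 0.14, adjusted p = 0.032). Higher were ssa-miR-22b-5p (0.96 ± 0.19, adjusted p = 0.0286), ssa-miR-8159-5p (0.58 ± 0.13, adjusted p = 0.0325) and efu-miR-27b of the miR-23/24/27 cluster (0.57 ± 0.14, adjusted p = 0.0464). Over all names, ipu-miR-222a was counted at 21308, 24571 and 28851 in the controls and at 0 in the exposed libraries, at least 10700-fold lower (adjusted p = 0.000645). The same name was at 22364, 0 and 0 in the unexposed source controls, and ssa-miR-222a-5p, another name of miR-222a, was at 3824 ± 120 and 4484 ± 145 CPM in slick controls and exposed libraries (0.23 ± 0.11, not called). oha-miR-1306-5p was also at 0 there, at least 60.2-fold lower (adjusted p = 0.0338).

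Of the lists at 5.00% slick oil, the miR-23/24/27 cluster had 6 of 7 positive log2 fold changes and a median of 0.42, with 1 name called and 3 adjusted over the list alone; its 2 miR-24 names share most of their counts. Its camera adjusted p was 0.0186, and 0.713 with an estimated correlation (0.00641 and 0.806 over all names). The blood cell and vessel list had 1 of 5 names lower, ssa-miR-144-3p, and the other 4 at negative values that were not called. The let-7 list had 0 of 5 called, with a median of 0.10 that turned to -0.04 under library totals alone, and a mean of -0.02. None of the 4 sensory organ names was called (1 lower adjusted over the list alone). Of 8 nervous system names 1 was lower and of 10 miR-17-92 names 1, both named above (3 and 1 adjusted over the list alone).

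Overall edgeR called 3 higher and 3 lower of 109 names counted in every library at 5.00% slick oil, and over all 149 names 0 higher and 3 lower. DESeq2 called 12 and 21, the authors' deposited table had 10 higher and 11 lower, and library totals alone gave 0 higher and 3 lower of the names counted in every library, with a median of -0.13 (-0.16 over all names). The 6 calls became 1, 15 and 1 without control 1, 2 or 3, 3, 1 and 1 without exposed library 1, 2 or 3, and 1 with all 12 libraries. The 3 calls over all names became 0 without any 1 control, 6 without exposed library 2, 1 without a count filter and 0 with all 12 libraries. ssa-miR-144-3p was called in all 6 fits that left out a library with names counted in every library, and in 1 of 6 over all names.

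At 2.50% slick oil edgeR called 0 of 156 names, with 4 at an unadjusted p under 0.05, and DESeq2 called 1. It called 0 of the 117 names counted in every library, with 8 unadjusted, and DESeq2 called 0. ssa-miR-144-3p was at 364 ± 33.0 CPM in the controls and 186 ± 70.3 in the exposed libraries (-0.97 ± 0.31, adjusted p = 0.656), and the epidermal pma-miR-203a-3p at 0.88 ± 0.30. ssa-miR-734-5p was at 0.67 ± 0.24, ola-miR-130c at -0.67 ± 0.25 and sha-miR-135a at 0.98 ± 0.38, each with adjusted p = 0.656. No list was called. The spread of log2 CPM within a group was widest here, and the count over all names was 2 without exposed library 1 and 2 without exposed library 2. The authors' deposited table had 4 higher and 1 lower names.

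At 1.25% slick oil the single call over all 159 names was fru-miR-216a, counted at 713, 771 and 1074 in the controls and at 0 in the exposed libraries, at least 682-fold lower (adjusted p = 0.00517). This name was at 636, 592 and 0 in the unexposed source controls. With names counted in every library edgeR called 0 of 117, with 3 at an unadjusted p under 0.05, and DESeq2 called 1. The smallest p-values there were those of ssa-miR-734-5p (0.96 ± 0.19, adjusted p = 0.0952), ssa-miR-8159-5p (0.43 ± 0.14, adjusted p = 0.726) and efu-miR-27b (0.59 ± 0.21, adjusted p = 0.751). All 5 let-7 names, 2 of which have nearly the same counts, had positive log2 fold changes with a median of 0.26 and 0 calls, also adjusted over the list alone. Camera gave this list an adjusted p of 0.0494, and 0.89 with an estimated correlation. The call over all names was absent without control 2 or 3 (0 calls each), there were 2 and 3 calls without exposed library 1 or 3, and DESeq2 gave 3. With names counted in every library the count was 2 without exposed library 1. The authors' deposited table had 2 higher and 1 lower names.

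The slope on concentration asked which miRNAs changed in steps with the dose of an oil. ssa-miR-144-3p decreased with both oils. In slick oil it was at 397 ± 23.9, 326 ± 61.8, 204 ± 80.5 and 137 ± 25.6 CPM at 0, 1.25%, 2.50% and 5.00%, a slope of -1.59 ± 0.27 log2 units per highest concentration (adjusted p = 0.00245, names counted in every library). In source oil it was at 260 ± 27.5, 227 ± 21.7, 176 ± 11.7 and 133 ± 4.43 CPM, a slope of -0.99 ± 0.11 (adjusted p = 1e-05). Also decreasing in source oil were ola-miR-184-5p (from 12310 ± 1850 to 5938 ± 506 CPM, adjusted p = 0.000133), chi-miR-182 (-0.44 ± 0.08), ssc-let-7i (-0.57 ± 0.10), ipu-miR-375 (-0.50 ± 0.09) and ola-let-7g (-0.45 ± 0.09). Increasing were ola-miR-19b (0.88 ± 0.13, adjusted p = 0.000125), dre-miR-93 (0.66 ± 0.12) and ola-miR-106a (0.60 ± 0.12).

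**Figure D2:**
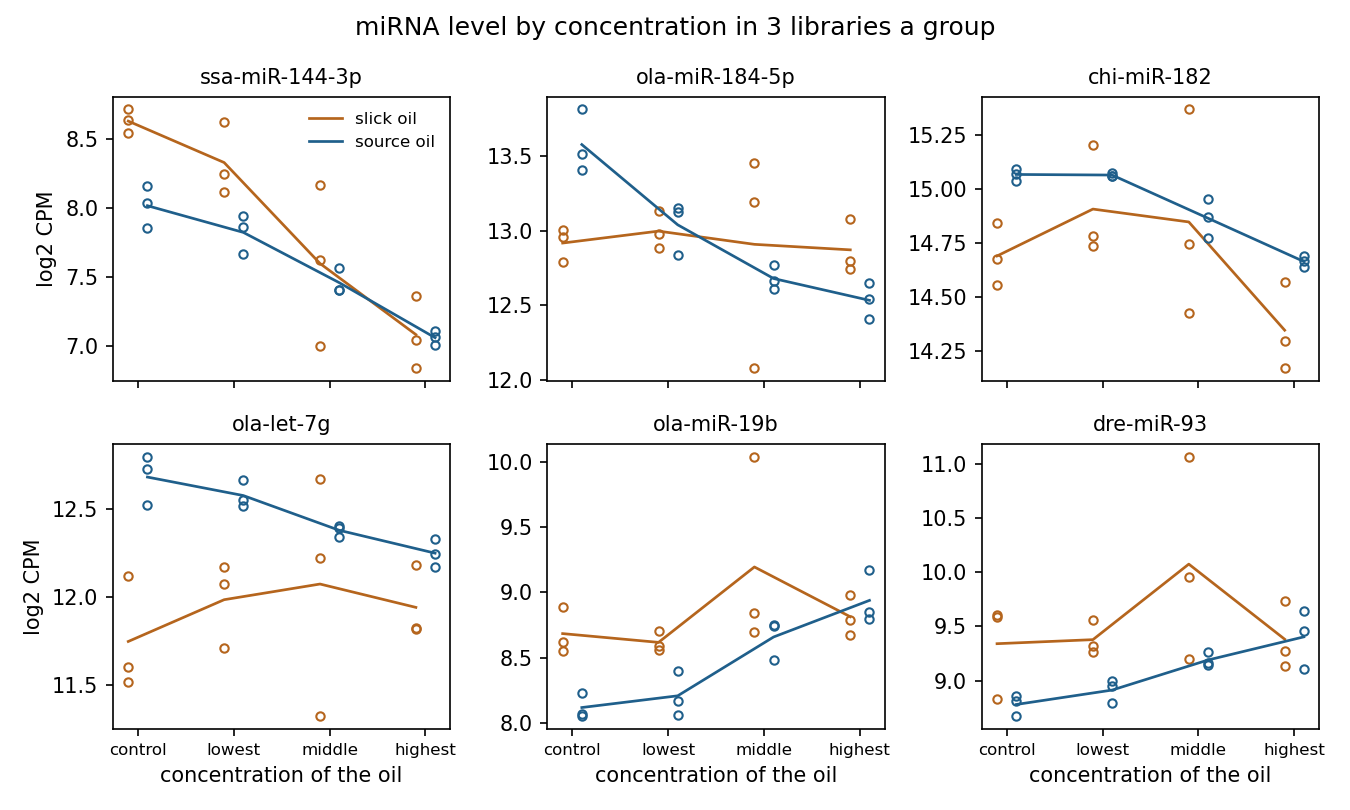
Level in log2 CPM (vertical axis) of 6 miRNA names in each library by concentration of oil (horizontal axis: control, lowest, middle, highest), with 3 points per group for slick oil (brown) and source oil (blue) and lines joining the group means. The oils were normalised separately, so levels are compared within an oil. ssa-miR-144-3p falls with both oils, from 397 to 137 CPM in slick and from 260 to 133 CPM in source oil, whereas ola-miR-184-5p falls in source oil.

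In source oil 30 names increased and 27 decreased of 109 counted in every library, and 22 and 27 of 167 over all names, 46 of which were shared. Under library totals alone the splits were 49 and 10, and 40 and 5, with medians of 0.35 and 0.24. In slick oil ssa-miR-144-3p was the single call in both sets of fits (of 100 and of 162 names), also under library totals alone, where the medians were -0.14 and -0.18. The slick call over all names was lost (0 calls) without control 1, 2 or 3 or without 5.00% library 1 or 3, and DESeq2 gave 6. With names counted in every library there were 4 slick calls without 2.50% library 3. Over all names the 49 source calls became 20 without 0.54% library 1.

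Whether the oils acted differently was tested as the difference between the slick and the source response at the matched rank of concentration. At the highest rank ola-miR-204 had a response of 0.26 ± 0.19 to slick and -0.78 ± 0.12 to source oil, a difference of 1.03 ± 0.21 (adjusted p = 0.00887, names counted in every library). ola-miR-184-5p had responses of -0.12 ± 0.14 and -1.10 ± 0.12 (difference 0.99 ± 0.21, adjusted p = 0.00887). The 2 miR-124 names, of neurons, went the other way, with ola-miR-124-5p at -0.66 ± 0.17 in slick and 0.25 ± 0.10 in source oil (difference -0.92 ± 0.21, adjusted p = 0.0122). dre-miR-124-4-5p differed by -0.94 ± 0.22, ola-miR-17 by -0.98 ± 0.24, mdo-miR-128a-5p by 1.20 ± 0.30, ssa-miR-222a-5p by 0.92 ± 0.23 and ola-miR-100 by 0.83 ± 0.21 (adjusted p = 0.0128 for each). ssa-miR-144-3p, lower with both oils, had a response lower by a further 0.60 ± 0.21 log2 units in slick oil (adjusted p = 0.046). Its exposed groups differed by 0.06 and its controls by 0.67. Levels of the oils come from separate experiments, so these values cannot show whether the difference lay in the controls or in the responses.

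**Figure D3:**
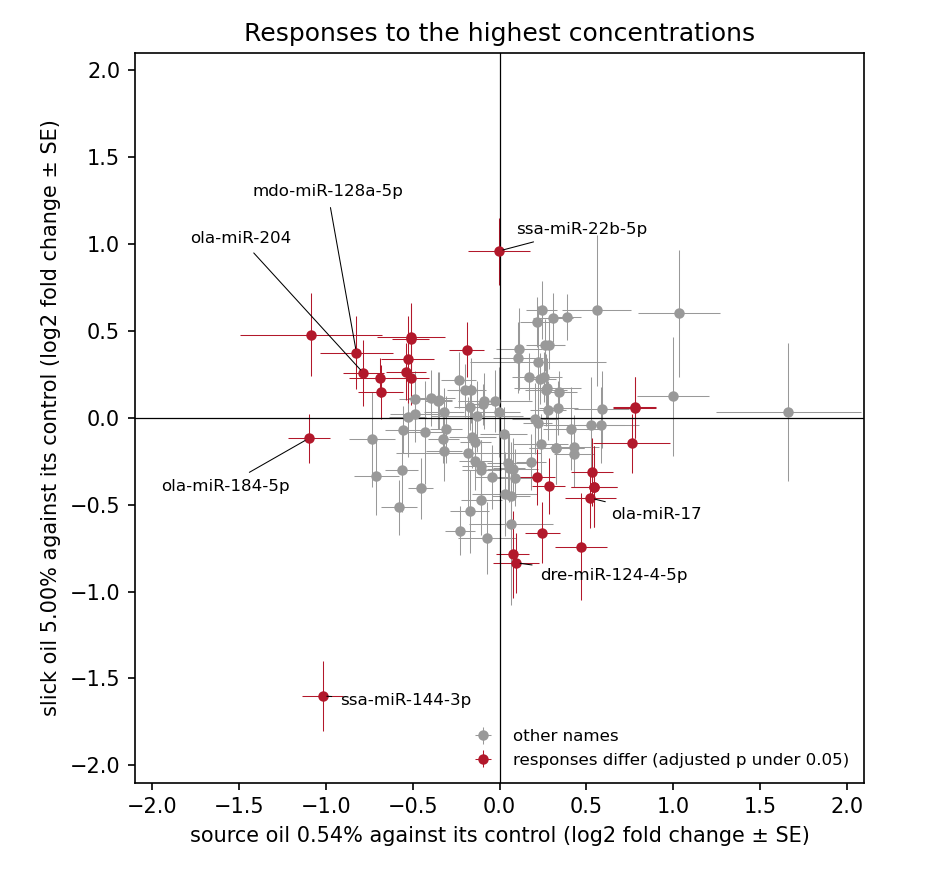
Log2 fold change against the control of each name counted in every library, for source oil 0.54% (horizontal axis) and slick oil 5.00% (vertical axis), with standard errors as bars. Red points are the 27 names whose responses differed between the oils (adjusted p under 0.05).

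With names counted in every library 27 of 107 responses differed, 13 with a positive and 14 with a negative difference, and over all names 4 of 133, all shared with the 27. These 4 were ola-miR-184-5p (0.95 ± 0.18), ola-miR-124-5p (-0.93 ± 0.18), ola-miR-181a-5p (-0.69 ± 0.14) and dre-miR-124-4-5p (-0.95 ± 0.20), each with adjusted p = 0.0296. Library totals alone moved the median difference to -0.36 and the split to 5 positive and 35 negative, and over all names to 0 and 1 with a median of -0.47. RLE size factors gave 1 positive and 0 negative difference over all names. DESeq2 gave 28 calls in either direction with names counted in every library and 41 over all names. The 27 became 16 without slick control 3 and 14 without source control 2. The 4 became 14, 8 and 0 without slick control 1, 2 or 3, 0, 18 and 2 without slick 5.00% library 1, 2 or 3, 0 and 0 without source control 2 or 3, and 0, 0 and 8 without source 0.54% library 1, 2 or 3.

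At the lowest and middle ranks edgeR called 0 differences between the oils in either set of fits. Unadjusted p under 0.05 were 7 of 135 and 8 of 112 names at the lowest rank, and 8 of 135 and 8 of 111 at the middle rank. DESeq2 called 1 and 0 at the lowest and 3 and 0 at the middle rank. Without slick 2.50% library 3 the middle rank had 1 call over all names and 10 with names counted in every library.

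The unexposed larvae of both experiments also differed. ssa-miR-734-5p was at 2678 ± 383 CPM in the slick and 6975 ± 893 CPM in the source controls (-1.38 ± 0.15, adjusted p = 0.000115, names counted in every library). Lower in the slick controls were also efu-miR-27b (-1.08 ± 0.13), oan-miR-458-5p (-1.49 ± 0.20), ipu-miR-375 (-0.90 ± 0.12), oar-miR-23b (-0.87 ± 0.13), ssa-miR-8159-5p (-0.77 ± 0.12) and ola-let-7g (-0.95 ± 0.16). The sensory organ and eye names lower at 0.54% source oil were also lower in the slick controls. They were ola-miR-184-5p (-0.70 ± 0.14), ola-miR-204 (-0.48 ± 0.13) and chi-miR-182 (-0.40 ± 0.12), with adjusted p of 0.0027, 0.00984 and 0.0144 (edgeR). ssa-miR-144-3p, lower with source oil, was higher (0.58 ± 0.15), and chi-miR-451-5p was not called. Source oil 0.54% and the slick controls are set against the same source controls here. Over all names aca-miR-199a-5p was higher (0.54 ± 0.07, adjusted p = 0.0108). The counts were 21 higher and 25 lower of 103 names counted in every library, and 6 and 19 of 119 over all names, all 25 of which were shared. DESeq2 called 45 over all names. Library totals alone gave 27 and 22, and 2 and 6, with a median of 0.17. The 25 calls became 11 without slick control 3 and 16, 6 and 16 without source control 1, 2 or 3.

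The log2 fold changes of the 3 source concentrations were alike across names. Names counted in every library are not independent replicates, and the comparisons share their controls, so each r stands beside that of simulated unchanged groups. Pearson's r was 0.92 between 0.27% and 0.54% (simulated 0.51; covariance 0.164 against 0.017 simulated), 0.80 between 0.135% and 0.27% (0.52; 0.068 against 0.018) and 0.70 between 0.135% and 0.54% (0.52; 0.067 against 0.018). At 0.27% and 0.54%, 10 names were higher and 15 lower in both, where independent lists give 1.95 and 3.54. With 3 controls no split into sets of at least 2 was possible, so part of the excess may come from the shared controls. Among slick concentrations r was 0.37, 0.38 and 0.33, below the simulated 0.49 to 0.50, with covariances of 0.039, 0.037 and 0.053 against 0.064, 0.066 and 0.068.

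Between the oils, which do not share controls, r was 0.24, 0.22 and 0.06 at the lowest, middle and highest rank. At the highest rank 44.8% of 105 names had the same sign. Only ssa-miR-144-3p was lower and only ssa-miR-8159-5p higher in both slick 5.00% and source 0.54% among names counted in every library, where independent lists give 0.74 and 0.57. The slick call of ssa-miR-8159-5p was lost under library totals alone (adjusted p = 0.116), with all 12 libraries (0.298) and without control 1 or 3 or exposed library 2 or 3 (0.0765, 0.114, 0.101 and 0.117). Over all names ssa-miR-144-3p was the 1 name lower in both, and 0.14 would be shared by independent lists.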

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

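Of the tests in this part, the one on larger spread was chosen only after the result was seen; those on depth, on the controls and on splits were written before, but not the fits to names counted in every library to which they were also applied.

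The flag for a closer look was a tested difference between the responses to the 2 oils at their highest concentrations. It was met by 4 names over all names, ola-miR-184-5p (0.95), ola-miR-124-5p (-0.93), ola-miR-181a-5p (-0.69) and dre-miR-124-4-5p (-0.95), each as slick minus source log2 response. It was met by 27 of the names counted in every library. The 10 with the smallest adjusted p were ola-miR-204 (1.03), ola-miR-184-5p (0.99), ola-miR-124-5p (-0.92), dre-miR-124-4-5p (-0.94), ssa-miR-222a-5p (0.92), ola-miR-17 (-0.98), mdo-miR-128a-5p (1.20), ola-miR-100 (0.83), mdo-miR-10b-5p (0.98) and dre-miR-2187-5p (-1.23). These 10 were called in each of the 12 fits that left out a library, and all kept their sign under library totals alone.

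The differing responses could reflect the oils or the unlike controls of the 2 experiments. Of the 27 names, 14 (51.9%, 95% confidence interval 31.9% to 71.3%) differed more between the exposed groups than between the control groups. The interval takes names as independent although the miR-722 and miR-19 pairs, and the miR-10b pair outside the slick controls and 1 slick library, have nearly the same counts. A constant difference in level between the experiments would shift both differences, so the tally cannot separate the explanations. A part from the controls stays open. Among the others were ola-miR-184-5p (0.37 between the exposed groups, -0.60 between the controls), dre-miR-124-4-5p (-0.40, 0.51), ssa-miR-222a-5p (0.34, -0.56) and ssa-miR-144-3p (0.06, 0.67). Splitting the libraries at random gave at least 27 calls in 1 of 100 splits, the real one, with 23 as the highest other. Over all names at least 4 calls came in 3 of 100 splits, with 17 as the highest other.

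Source oil 0.54% gave 47 and slick oil 5.00% gave 6 calls among names counted in every library. Lower depth of the slick libraries was not the cause, since the source libraries thinned to a total of 2820454 still gave 51 calls. A larger spread between the slick libraries may account for part of it. The spread of log2 fold changes, corrected for standard errors, was 1.41 times as large in source as in slick oil, but between 1.05 and 1.83 times when 1 library was left out. The concentrations of the 2 oils were not matched in any way other than rank, so a difference in strength of the oils was not tested.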

How the results depend on the processing

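Of the results for single names under alternative settings, 2079 stayed on their side of the threshold, 36 moved past it, 470 no longer passed it and 0 reversed. Of the counts of calls, list calls and correlations, 309 stayed the same and 145 moved, and for each of these the cause was not tested unless fewer libraries or names show it. The fits to names counted in every library were chosen after seeing the data. Main counts over all names are 1, 0 and 3 for slick oil from low to high, 2, 2 and 22 for source oil, 0, 0 and 4 for the oil difference, 1 and 49 for the slopes and 25 for the controls. Among names counted in every library they are 0, 0 and 6, then 0, 27 and 47, then 0, 0 and 27, then 1 and 57, and 46.

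Over all names, DESeq2 gave 3, 1 and 21 for slick oil, 23, 31 and 64 for source oil, 1, 3 and 41 for the oil difference, 6 for the slick slope and 45 for the controls. An adjusted p under 0.10 gave 9 at slick 5.00%, 18 at source 0.27%, 44 at source 0.54%, 27 for the highest oil difference and 41 for the controls. No filter gave 1 at slick 5.00%, 1 at source 0.27%, 5 at source 0.54% and 9 for the highest oil difference, where at least 50 counts gave 16 and RLE size factors 1. Library totals alone gave 10 at source 0.27%, 1 for the highest oil difference and 8 for the controls. All 12 libraries of the oil gave 0 at slick 1.25%, 0 at slick 5.00% and 1, 13 and 34 for source oil.

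Among names counted in every library, DESeq2 gave 1 at slick 1.25%, 12 at slick 5.00% and 13 at source 0.135%. An adjusted p under 0.10 gave 1, 11 and 10 there, all 12 libraries gave 1 at slick 5.00% and 1 at source 0.135%, and library totals alone gave 3 at slick 5.00%.

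The replicate number as a block gave, over all names, 0 calls at slick 1.25% and 5.00%, 0 at each source concentration, 11 for the highest oil difference and 11 for the controls. Among names counted in every library the block gave 2 at slick 1.25% and 1 at source 0.27%. It moved no other count by over 1.5 times. Only at slick 2.50% did every same-numbered pair correlate over 0.1, and there the block changed no call. Same-numbered libraries correlated at 0.07, -0.08 and 0.10 for slick 1.25%, -0.03, 0.18 and 0.01 for slick 5.00%, -0.03, 0.01 and -0.16 for source 0.135%, -0.04, 0.20 and -0.34 for source 0.27% and 0.43, 0.21 and 0.09 for source 0.54%. In none of these 5 comparisons did every library correlate best with its own number. No pairing was assumed there, although 3 libraries a group cannot exclude it.

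With 1 library left out, counts over all names ranged from 0 to 3, 0 to 2 and 0 to 6 for slick oil, 0 to 4, 0 to 6 and 0 to 28 for source oil, 0 to 1 and 0 to 18 for the middle and highest oil difference, 0 to 1 and 20 to 48 for the slopes, and 6 to 36 for the controls. Among names counted in every library they ranged from 0 to 2 at slick 1.25%, 1 to 15 at slick 5.00%, 0 to 9, 1 to 43 and 27 to 50 for source oil, 0 to 10 and 14 to 36 for the middle and highest oil difference, 1 to 4 and 44 to 63 for the slopes and 31 to 48 for the controls.

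Camera called 0, 1, 1, 3 and 2 lists over all names at slick 1.25%, slick 5.00% and the 3 source concentrations, and 1, 1, 1, 2 and 3 among names counted in every library. With an estimated correlation it called 0 in each. Fry called 1, 0 and 4 over all names at slick 1.25%, slick 5.00% and source 0.135% and 6 at source 0.54%, and 0, 0, 3, 4 and 6 among names counted in every library. With the replicate block camera called 0 at slick 1.25% among those names.

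Correlations over all names moved to those of names counted in every library from 0.04 to 0.38 between slick 1.25% and 5.00%, from 0.12 to 0.24 between the lowest ranks of the oils, from 0.19 to 0.06 between the highest and from 0.77 to 0.92 between source 0.27% and 0.54%. In the authors' deposited table the last were 0.06 and 0.99, and source 0.135% against 0.54% was 0.74 where all names gave 0.63. Depth was lowest at slick 5.00% (2820454 to 4346165 counts). Planted 1.5-fold changes among names counted in every library were recovered in 2% to 54% of cases for slick oil and in 85.5% to 90% for source oil.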

Other observations

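Of the tests in this part, those on reads under another name, on loss, on too few reads and on delayed development were chosen only after the result was seen; the splits were written before, but not the fits to names counted in every library.

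Names listed at 0 in some libraries and at high counts in others were common, such as tni-let-7d, at 61026, 61584 and 51151 counts in the source controls and 0 in all 9 exposed source libraries, and ola-miR-128, at 261002, 546953 and 0 counts in the slick controls. For names of 1 miRNA number with nearly equal counts in control 1, the other name still held a count in 317 of 535 cases (59.3%). This was below the 88.3% of 967 cases in pairs of different miRNAs chosen the same way. The test does not support reads carried under another name of the same miRNA, but it cannot decide against them. Names of 1 miRNA that are at 0 together lower the share, and controls 2 and 3 enter once per table. In the slick controls mdo-miR-128a-5p was at 260984, 546945 and 460802 counts, so where ola-miR-128 was at 0 this name was not. This explanation stays open. Loss after exposure was not the general cause, since exposed libraries had on average 2.06 more names at 0 than controls 2 and 3 (SD between libraries 4.53), but it stays open for single names such as tni-let-7d and for slick oil 5.00%, with 57.0 against 46.5 such names (SD 8.23). Too few reads were not the general cause either, as 82.6% of 1482 zeros had an expected count of at least 100. The cause of the zeros stays open.

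Lower let-7 names (5 of 5, and 2 under library totals alone, camera adjusted p = 0.475 with an estimated correlation) and higher miR-17-92 names (6 of 10, with 2 lower, camera adjusted p = 0.12) at 0.54% source oil could be a sign of delayed development. If so, the early embryonic ola-miR-430a should be higher, and its log2 fold change was 0.34 ± 0.11 (adjusted p = 0.0405 among names counted in every library). The slope on source concentration was 0.35 ± 0.14 (adjusted p = 0.041). The support is thin, because over all names the adjusted p was 0.102, and with 1 library left out it passed only without 0.54% library 3 (adjusted p = 0.0115). At 5.00% slick oil the value was 0.06 ± 0.16, and the stage of the larvae was not measured here. A similar pattern separated the unexposed larvae of the 2 experiments among names counted in every library. In slick against source controls ola-let-7g was at -0.95 ± 0.16, ssc-let-7i at -0.90 ± 0.22 and ola-miR-19b at 0.55 ± 0.14. There ola-miR-430a was at 0.55 ± 0.13 (adjusted p = 0.00532, edgeR), and sha-miR-92a was lower, as with source oil (-0.66 ± 0.14). Both contrasts subtract the same 3 source control libraries, so a trait of those libraries would give the pattern in each. The match therefore cannot show that the pattern arose apart from oil.

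With 10 splits of 6 libraries there are too few for a share under 0.05. A real count of 0 is reached by any split, so those tallies decide nothing. At least as many calls as in the real groups came in 9 of 10 splits at 1.25% slick oil (1 call, highest other 7), 10 at 2.50% (0, 2), 2 at 5.00% (3, 3), 4 at 0.135% source oil (2, 5), 6 at 0.27% (2, 3) and 1 at 0.54% (22, 3). Among names counted in every library they came in 10, 10 and 1 of 10 splits for slick oil (0, 0 and 6 calls) and in 10, 1 and 1 for source oil (0, 27 and 47 calls), with 0 as the highest other each time. The difference between the controls came in 1 of 10 splits in both sets of fits (25 and 46 calls, highest other 1 and 0).

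Of 100 splits, all 100 gave at least the 0 calls of the oil difference at the lowest rank (highest other 6, and 5 among names counted in every library) and all 100 at the middle rank (2 and 3), as any split must. The slick slope had at least its 1 call in 15 of 100 splits over all names (highest other 1) and in 3 of 100 among names counted in every library (highest other 5). The source slope had its 49 and 57 calls in 1 of 100 splits each, with 3 and 7 as the highest other.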
